A study of Homo sapiens with 2 samples.

How the data were processed

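Total RNA of parental MCF-7 cells and of the radioresistant MR cells derived from them was labelled with biotin from 200 ng per sample and hybridised to Affymetrix whole-transcript arrays, with 1 array per group. The deposited values were RMA signals on the log2 scale, as the authors made them; per the submitters' processing notes the tool was RMA (robust multi-array average), which corrects background, normalises the arrays to each other and summarises the probes of a probe set, with no version given. The file does not write out the base of the logarithm. It was read as log2 because RMA works on that scale and because the values ran from 0.21 to 13.33. No further logarithm, pseudocount or scaling was applied to the main values. The genome build and annotation release behind the probe sets were not given in the sources used here.

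The 44629 probe sets were joined to genes through the array's annotation table. A probe set was used where the table gave exactly 1 gene symbol, which held for 15835 probe sets, or 35.5%. The other 28794 carried no symbol there and entered no gene value. All gene identifiers were found in the RefSeq gene table, which served for current symbols, gene type and the order of genes along chromosomes. The probe sets of a gene were averaged, which gave 14812 genes, 651 of them with more than 1 probe set. The difference of a gene was its radioresistant minus its parental log2 signal. Genes counted by size were the 7414 whose mean over both arrays was at or above the median over genes, a log2 signal of 4.32.

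With 1 array per group there is no spread between replicates, so no test was run between the groups and no p-value is given for any gene. Genes were counted as higher or lower where the log2 difference was at least 1 in size, which is 2-fold. For gene lists, the median difference of the measured members was placed among the medians of 10000 random lists of the same size. Random lists were drawn within 20 bins of the mean level of both arrays, without the list's own genes. A list is said to stand apart where its percentile was under 2.5 or over 97.5. This percentile describes these 2 arrays and takes no account of how genes vary together, so it is not a test of the groups. A second percentile used random lists matched on the parental level. Lists with fewer than 5 measured genes were given no percentile.

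The groups, the size rule, the 31 gene lists, the rule for named genes and all alternatives except those named here were fixed before the data were examined. The lists covered estrogen receptor response, p53 targets, interferon-stimulated genes, antigen presentation, the DNA repair pathways, G1/S and G2/M genes, luminal, basal and mesenchymal genes, stemness, the ERBB2 amplicon and the ERBB family. They also covered NRF2, hypoxia and glycolysis, NF-kB and secretory genes, drug efflux, apoptosis, cholesterol and fatty acid genes, the unfolded protein response, oxidative phosphorylation, ribosomal proteins, replication-dependent histones, housekeeping genes and WNT and TGF-beta targets. Markers of fibroblasts, leukocytes and endothelial cells stood for cells that a culture of MCF-7 should lack. Named genes were the 15 with the largest difference in each direction among the counted genes, up to 4 members of each list with the largest absolute difference, and 11 genes named whatever their value. These were ESR1, PGR, ERBB2, EGFR, TP53, CDKN1A, MKI67, CD44, CD24, VIM and CDH1. Clone names, LOC numbers, symbols starting with MIR, SNOR, RNU or RNA5S and open-reading-frame placeholders were counted but passed over for naming; other small RNAs, such as SNAR-F and SCARNA11, were not passed over. ERBB2, TP53, CDKN1A and CDH1 had no probe set named in the annotation table and were not analysed here.

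Alternatives were quantile normalisation of both arrays, equal array medians, removal of the trend of the difference on the mean by loess (fraction 0.3), other filters on level, the brightest probe set of a gene, each probe set on its own, thresholds of 1.5-fold and 3-fold, the mean of a list, and random lists without matching. Matching on the parental level, leaving out genes with the same value on both arrays, and protein-coding genes only were added after the data were seen. On simulated data with 14812 genes and noise of SD 0.5, the size rule found 46% of genes changed by a log2 of 1 and 97% of genes changed by 2, and it took in 2.31% of unchanged genes in the upward direction. Of 200 simulated lists of 25 genes without a shift, 3.5% stood apart, against 100% of lists shifted by -1. The simulated noise was independent between genes and gave no identical values, and matching on the parental level was not simulated. These shares therefore do not give the rate of false calls on the real arrays.

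Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9. For arrays, precision is limited by their number.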

Results

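The series asked which genes differ in expression between breast cancer cells sensitive to radiation and cells that had become resistant to it. MCF-7 is an established line from a pleural effusion of a breast carcinoma and is ordinarily known as luminal and estrogen receptor positive, without amplification of ERBB2. The parental cells, the radiosensitive group, were compared with MR cells, which had been selected from them by repeated irradiation and recovery and had shown resistance in colony forming assays per the labels. Both were grown in medium with 10% serum. The labels do not give 1 dose: the design and the sample characteristics give 5 Gy per irradiation, 2 times a week, the treatment protocol gives 4 Gy and names other cells, and the source name gives 48 Gy. The source names also call both samples HER2-positive, the protein product of ERBB2. There was 1 array per group and no replicate, so each difference below is between 2 single arrays and none has a replicate error.

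Each array gave 44629 probe sets. The parental array had a median log2 signal of 3.58, a 99th percentile of 8.0 and an SD over probe sets of 1.67. The radioresistant array had a median of 3.71, a 99th percentile of 6.92 and an SD of 1.45. A signal of at least 8 was read by 452 probe sets on the parental array and 144 on the radioresistant array. The deposited values thus do not share one distribution, although RMA normalises arrays to each other, and the step behind this is not known. Across probe sets, which are not independent replicates, the arrays correlated with a Pearson r of 0.807 and a Spearman rho of 0.841. The same value on both arrays was given for 12074 probe sets (27.1%) and 3490 genes (23.6%), which count below as within 2-fold.

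The radioresistant cells had lower signal for the genes of mitosis and of DNA double-strand break repair, and higher signal for a smaller set that held NFIX, TCF4, MSN and VIM. Many estrogen-responsive and luminal genes were lower as well. The estrogen receptor list stood apart at equal mean level (percentile 0.51) but not at equal parental level, and the luminal list stood apart at neither. Matching on the parental level was added after the data were seen and uses a term of the difference itself. Ribosomal protein and housekeeping genes were lower by about as much. CD24, a surface glycoprotein of luminal cells, read 9.10 in parental and 3.12 in radioresistant cells, a log2 difference of -5.98. MKI67, which encodes the proliferation marker Ki-67, read 7.23 and 4.40, a difference of -2.83. VIM, which encodes the mesenchymal filament protein vimentin, read 4.16 and 5.78, a difference of 1.62. Of the 7414 genes counted, 529 (7.14%) were at least 2-fold higher in radioresistant cells, 2185 (29.5%) were at least 2-fold lower and 4700 (63.4%) were neither. The split between directions depended on scaling: after quantile normalisation the counts were 937 higher and 1697 lower.

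Among genes higher in radioresistant cells, the small non-coding RNA SNAR-F had the largest difference of the named genes, 4.06, from 5.19 to 9.25. NFIX, a transcription factor of the nuclear factor I family, was 11.1-fold higher, with 4.53 in parental and 8.0 in radioresistant cells. TCF4, a basic helix-loop-helix factor, read 3.95 and 6.36, a difference of 2.41, and ATOH1, another factor of that class, had a difference of 2.34. MSN encodes moesin, which links the plasma membrane to actin, and read 4.32 and 6.50, a difference of 2.18. The chemokine gene CCL17 had a difference of 2.01, OBP2A, an odorant-binding protein gene, 2.06, NYAP1 2.11, LIX1L 2.66 and the Cajal body RNA SCARNA11 2.74. The remaining 5 were the keratin-associated protein genes KRTAP5-1 (2.11), KRTAP10-9 (2.05) and KRTAP9-8 (2.01), FAM27E5 (2.71) and the pseudogene NF1P2 (2.01). These and SNAR-F belong to groups of near-identical copies, whose probes may not tell members apart. A further 15 microRNA genes had differences as large and were passed over for naming. Some named genes had low parental values, such as LIX1L (3.18), ATOH1 (3.43) and KRTAP9-8 (3.45), under the parental array median of 3.58. Their differences are not exact sizes, as signal over background was not analysed.

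Among genes lower in radioresistant cells, the differences were larger. The abundant nuclear and cytoplasmic long non-coding RNAs MALAT1 and NORAD had differences of -5.41 and -6.46. NORAD read 9.84 in parental and 3.38 in radioresistant cells, and the 3 probe sets of MALAT1 differed by -4.14, -4.51 and -7.59. DSCAM-AS1, a long non-coding RNA known from luminal breast cancer, had a difference of -6.14. BRIP1, a helicase that works with BRCA1, read 10.00 and 4.03, a difference of -5.97. The cell polarity gene PARD6B had a difference of -6.35, the heterochromatin protein gene CBX3 -6.00 and the ribosome maturation gene SBDS -6.20. RMRP, the RNA of the RNase MRP complex, had -5.53, the proteasome assembly gene POMP -5.40, OAZ1, which regulates polyamine synthesis, -5.37, the mitochondrial ribosomal gene MRPS21 -5.29 and RSL1D1 -5.27. RPL21P28 (-6.94) and NPIPB5 (-6.26) belong to families of near-identical copies. Signal over background was not analysed, so differences that involve very low values, such as the radioresistant ones of RPL21P28 (0.93), CBX3 (1.8) and SBDS (2.66), are not exact sizes; 12 of all 149 genes named by the rule read below the 25th percentile of an array (2.35 parental, 2.56 radioresistant). Removing the trend of the difference on signal level by loess moved 31 of all 149 genes named by the rule by more than 1.5-fold, among them NFIX to 4.11, BRIP1 to -4.85 and OAZ1 to -3.90.

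**Figure D1:**
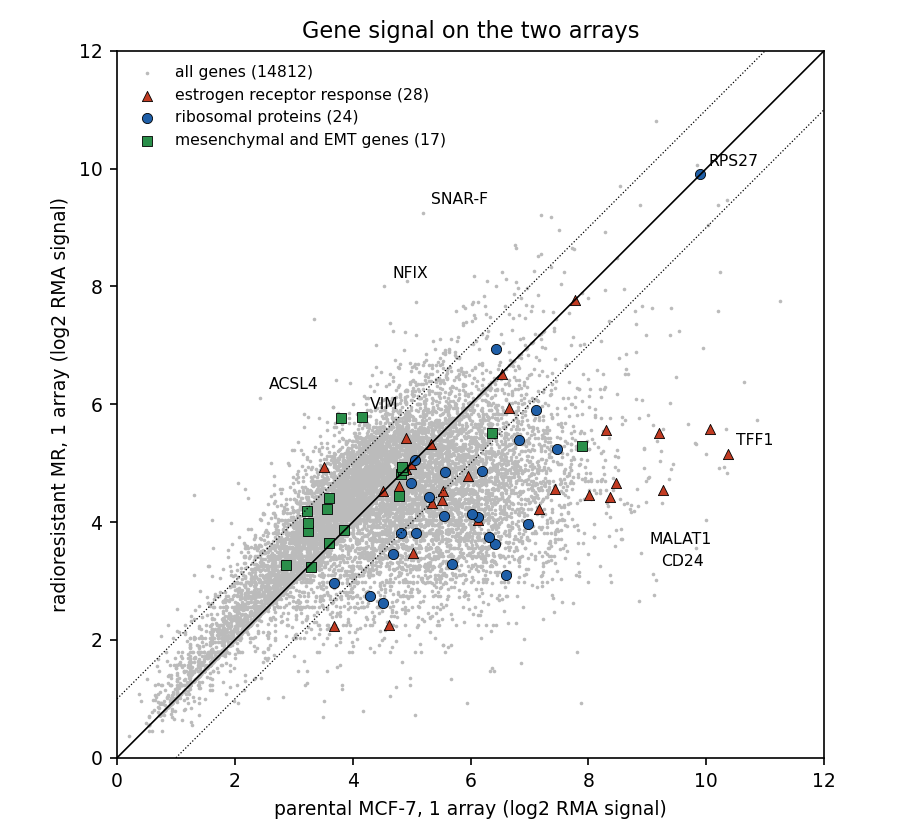
Log2 RMA signal of 14812 genes (grey points) on the parental array (x axis) and the radioresistant array (y axis), n = 1 array per group, with 28 estrogen receptor response genes (triangles), 24 ribosomal protein genes (circles) and 17 mesenchymal genes (squares); the solid line marks equal signal and the dotted lines 2-fold differences. TFF1 and CD24 lie far below the lower dotted line, NFIX, VIM, ACSL4 and SNAR-F above the upper one, and RPS27 (9.89 and 9.91) on the line of equality.

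Genes of the estrogen receptor response were lower in radioresistant cells. Of 28 measured, 18 were at least 2-fold lower, 1 was at least 2-fold higher and 9 were within 2-fold, with a list median of -1.30 (-2.09 without genes of identical value). The secreted trefoil factor TFF1, a classical estrogen target, read 10.37 in parental and 5.16 in radioresistant cells, a difference of -5.21. The transcription factor XBP1 had a difference of -4.72, the protease CTSD -4.48 and the receptor cofactor GREB1 -3.94. The receptor gene ESR1 itself read 5.53 and 4.53, a difference of -1.0, and the progesterone receptor gene PGR 5.03 and 3.47, a difference of -1.56. The list stood at percentile 0.51 among random lists of equal mean level. Among random lists of equal parental level, whose median was -1.08, it stood at percentile 27.3, so it did not stand apart from genes that were as bright in parental cells.

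Luminal epithelial markers read lower as well, with 12 of 21 at least 2-fold lower, none at least 2-fold higher and a median of -1.05, which became -0.30 after loess and -0.68 after quantile normalisation. The keratin gene KRT19 had a difference of -4.73, the adhesion molecule gene EPCAM -4.49, the epithelial splicing regulator ESRP1 -3.07 and the transcription factor GRHL2 -2.82. KRT18, chosen after its values were seen, had 2 probe sets that disagreed: 1 read 9.33 and 5.47, the other 11.15 and 11.03. The list did not stand apart at equal mean level (percentile 12.2) or at equal parental level (percentile 86.7).

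Mesenchymal genes went both ways. Of 17 measured, 2 were at least 2-fold higher, the receptor kinase gene AXL (3.8 and 5.77, a difference of 1.97) and VIM, whose 3 probe sets differed by 1.21, 2.44 and 1.21. THBS1, which encodes the matrix protein thrombospondin-1, was at least 2-fold lower, at -2.60, and TWIST2 differed by 0.96. The list median of 0.11 (percentile 81.2) changed sign after loess, to -0.01, and with equal array medians, to -0.02. Basal epithelial markers had a median of 0.14 over 10 genes (percentile 73.5), which became -0.09 after loess. KRT5 differed by 1.32, KRT14 by 0.48, KRT16 by 0.46 and SFN by -1.09.

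The 23 stemness and ALDH genes had a median of 0.00 (percentile 56.5), or 0.16 without genes of identical value, with 1 at least 2-fold higher and 3 at least 2-fold lower. CD24 and CD44 are used together to describe stem-like breast cancer cells. CD44 read 3.87 in parental and 3.77 in radioresistant cells, a difference of -0.10, beside the difference of -5.98 for CD24. The aldehyde dehydrogenase gene ALDH2 differed by 1.28, the receptor gene NOTCH2 by -2.41 and SOX2 by -1.79.

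Genes next to ERBB2 on chromosome 17, which rise together where it is amplified, showed no difference of 2-fold in any of 10 and had a median of 0.00 (percentile 55.4). However, 5 of the 10, GRB7 among them at 4.83, had identical values on both arrays, and without these the median was 0.33. TCAP differed by 0.76, PNMT by 0.56, CDK12 by 0.33 and STARD3 by 0.16. Of 12 genes of the ERBB family and its ligands, 3 were at least 2-fold lower and the median was 0.00 (percentile 31.5), or -1.11 over the members at or above the median level. These were the receptor genes ERBB4 (-1.76) and ERBB3 (-1.11) and the feedback inhibitor ERRFI1 (-2.66). NRG1, which encodes a ligand of these receptors, differed by 0.82 and EGFR by -0.11.

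DNA repair genes were lower in radioresistant cells, those of double-strand break repair most. Of 21 genes of homologous recombination, 14 were at least 2-fold lower, none at least 2-fold higher and the median was -2.10. BRIP1 differed by -5.97, RAD51C, a paralog of the recombinase RAD51, by -4.35, the resolvase GEN1 by -3.74 and RAD50, of the complex that senses DNA ends, by -3.68. Of 13 genes of non-homologous end joining and damage signalling, 11 were at least 2-fold lower and the median was -1.62. XRCC5 and XRCC6, which encode the Ku heterodimer that binds DNA ends, differed by -4.85 and -3.25, TOPBP1 by -2.68 and the checkpoint kinase gene ATR by -1.88. Both lists stood apart at equal mean level, at percentiles 0.00 and 0.07, and at equal parental level, at 0.00 and 1.78. Of 18 genes of base excision, nucleotide excision and mismatch repair, 10 were at least 2-fold lower and the median was -1.18. RAD23B differed by -4.02, the endonuclease gene APEX1 by -3.46, the mismatch repair gene PMS2 by -1.73 and the glycosylase gene NEIL3 by -1.63. That list stood apart at equal mean level (percentile 1.08) and not at equal parental level (7.28).

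Genes of the cell cycle were lower too. Of 31 genes of G2 and mitosis, 25 were at least 2-fold lower, none at least 2-fold higher and the median was -2.21. The cyclin gene CCNB1 differed by -4.76, the spindle checkpoint kinase gene TTK by -4.07, the mitotic kinase gene AURKA by -3.65 and NUSAP1 by -3.41. The list stood apart at equal mean level (percentile 0.00) and at equal parental level (0.70). Of 26 genes of the G1/S transition and replication, 16 were at least 2-fold lower and the median was -1.56, or -0.98 after quantile normalisation. DSCC1 differed by -3.75, the replication clamp gene PCNA by -3.59, the cyclin gene CCNE2 by -3.51 and the initiation factor gene MCM10 by -3.36. It stood apart at equal mean level (percentile 0.14) and not at equal parental level (30.1). The p53 targets had a median of -0.79 over 18 genes, with 7 at least 2-fold lower and none higher. Among them the kinase gene PLK2 differed by -3.29, the ribonucleotide reductase gene RRM2B by -2.32, the cytokine gene GDF15 by -2.24 and TRIAP1 by -1.86. They stood at percentile 1.97 at equal mean level and 6.73 at equal parental level.

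**Figure D2:**
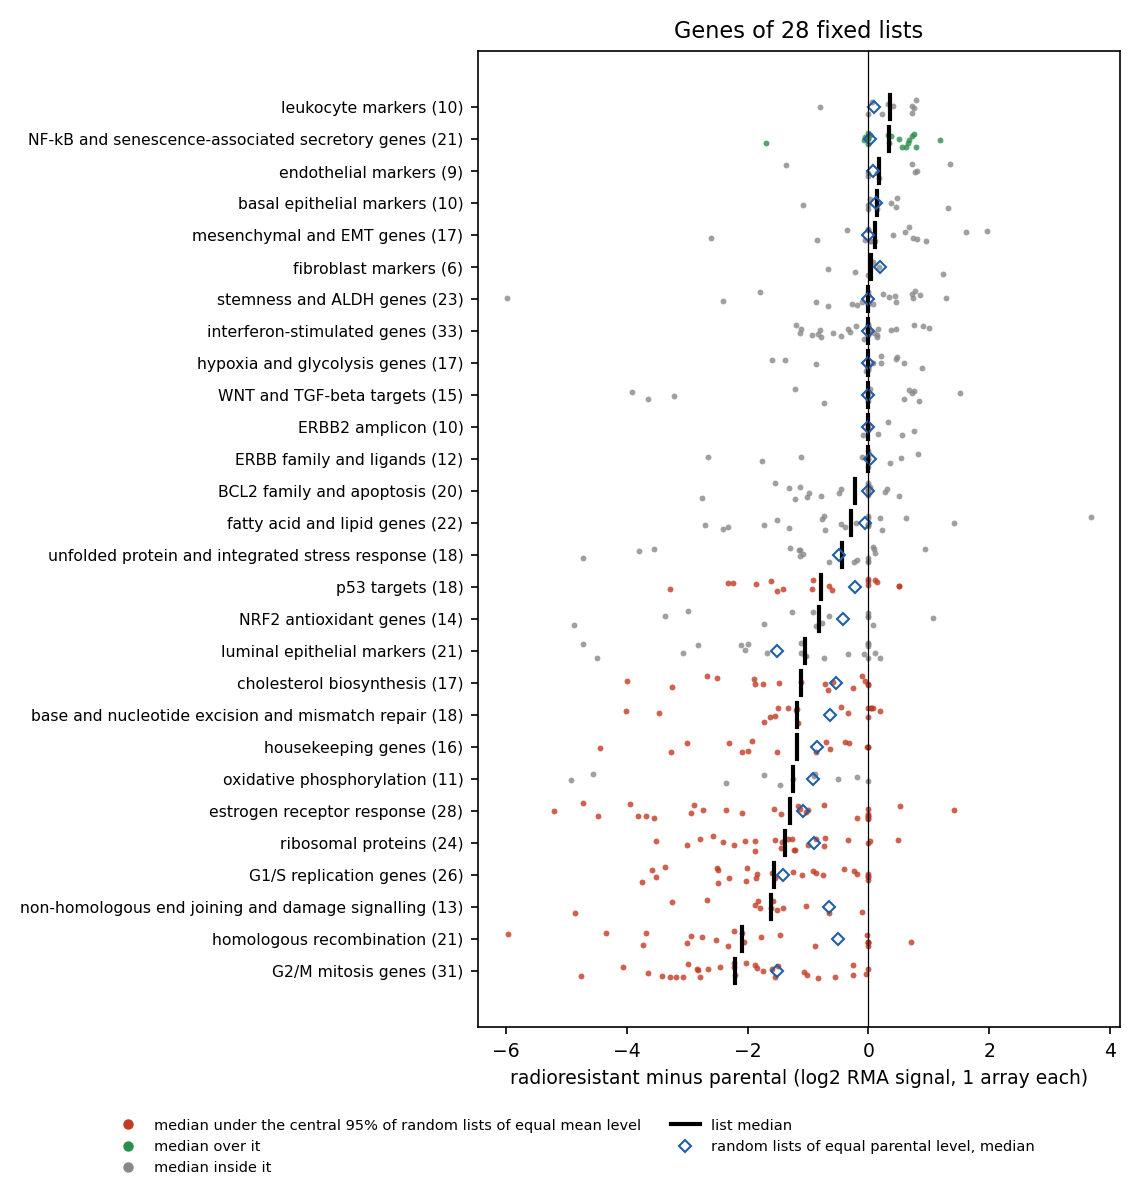
Radioresistant minus parental log2 RMA signal (x axis, n = 1 array per group) of the genes (points) of 28 fixed lists (y axis, number of measured genes in brackets), with each list's median (black bar) and the median of random lists of equal parental level (diamond). Colour gives the place of the list median among random lists of equal mean level: 10 lists lay under their central 95%, 1 over and 17 inside.

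Genes of translation and of common cell maintenance were among those that read lower. Of 24 ribosomal protein genes, 17 were at least 2-fold lower and the median was -1.38, with RPS15 at -3.51, RPL35 at -3.00, RPS24 at -2.79 and RPL6 at -2.57. RPS27, chosen after its values were seen, read 9.89 and 9.91. Of 16 housekeeping genes, 8 were at least 2-fold lower and the median was -1.19. LTAP1 differed by -4.44, the cyclophilin gene PPIA by -3.27, the elongation factor gene EEF2 by -3.01 and VPS29 by -2.30. The lists stood at percentiles 0.07 and 2.17 at equal mean level and at 7.64 and 20.3 at equal parental level.

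Metabolic genes were lower in part. Of 17 cholesterol biosynthesis genes, 9 were at least 2-fold lower and the median was -1.12, with the epoxidase gene SQLE at -4.00, DHCR7 at -3.25, INSIG1 at -2.67 and MSMO1 at -2.50. The list stood at percentile 0.74 at equal mean level and 7.54 at equal parental level. Of 11 oxidative phosphorylation genes, 6 were at least 2-fold lower, with a median of -1.24 that did not stand apart (percentile 5.98) and became -0.68 after quantile normalisation and -0.80 after loess. COX4I1 differed by -4.92, UQCRC2 by -4.56, COX7C by -2.35 and COX8A by -1.73, which became -0.23 after loess. The 22 fatty acid and lipid genes had a median of -0.30 (percentile 11), which ran from -0.73 without genes of identical value to -0.12 after quantile normalisation. ACSL4, which activates long-chain polyunsaturated fatty acids, read 2.43 in parental and 6.11 in radioresistant cells; the parental value lay near the 25th percentile of the array (2.35) and was not shown to be above background. CPT1A differed by -2.71, the desaturase gene SCD by -2.40 and PPARG by -2.32. The 17 hypoxia and glycolysis genes had a median of 0.00 (percentile 61.3), with LDHA at -1.59, HK1 at -1.38, MXI1 at 0.89 and GAPDH at -0.86. Their median was 0.21 without genes of identical value, 0.235 after quantile normalisation and -0.04 after loess.

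Of 14 antioxidant genes under NRF2, 5 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.81 that did not stand apart (percentile 4.62). The thioredoxin gene TXN differed by -4.88, the peroxiredoxin gene PRDX1 by -3.36, the glutathione reductase gene GSR by -2.99 and TXNRD1 by -1.72. The higher member was the heme oxygenase gene HMOX1, at 1.07, named after its value was seen. The 18 genes of the unfolded protein and integrated stress response had a median of -0.44 (percentile 21.8), which ran from -1.09 without genes of identical value to -0.29 after quantile normalisation, with XBP1 at -4.72, the chaperone gene CALR at -3.80, STC2 at -3.55 and ATF4 at -1.29. The 20 genes of the BCL2 family and apoptosis had a median of -0.22 (percentile 7.79), which ran from -0.89 without genes of identical value to 0.00 with the brightest probe set of each gene or with genes at or above the median level alone. Of these, 6 were at least 2-fold lower, among them the survival genes MCL1 (-2.75), BIRC5 (-1.55), BIRC2 (-1.31) and CFLAR (-1.22).

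Genes of NF-kB and the senescence-associated secretory group formed the 1 list that stood apart as higher. Their median was 0.34 over 21 genes (percentile 99), or 0.16 after loess and 0.53 without genes of identical value, with RELB, an NF-kB subunit, at 1.18, the growth factor gene CSF1 at 0.79 and the cytokine gene LIF at 0.76. NFKB1, another subunit, went the other way, at -1.69. Only RELB passed 2-fold upward, and at equal parental level the list stood at percentile 96.2, inside the central range. The 33 interferon-stimulated genes had a median of 0.00 (percentile 39.1), with EPSTI1 at 1.00, PLSCR1 at -1.20, DTX3L at -1.14 and HERC6 at -1.12. Of them 10 had identical values on both arrays, and without these the median was -0.21 (percentile 6.22). It was -0.11 after quantile normalisation and -0.21 after loess. The 15 WNT and TGF-beta targets had a median of 0.00 (percentile 56.3), with NOTUM at 1.52, DKK1 at -3.92, BAMBI at -3.65 and SKIL at -3.22.

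Markers of cells that the culture should lack had medians below the median gene on the parental array (4.31), and on the radioresistant array (4.21) those of leukocytes and endothelial cells lay above it. The 6 fibroblast markers had a median of 3.46 in parental and 3.50 in radioresistant cells and a median difference of 0.04 (percentile 44.2), with THY1 at 1.24, FBN1 at -0.67, ASPN at -0.22 and DCN at 0.17; it turned negative with each scaling tried. The 10 leukocyte markers had medians of 3.98 and 4.23 and a median difference of 0.36 (percentile 94.3; 0.09 after loess), with CSF1R at 0.79, TYROBP at 0.76, CD4 at 0.73 and CD68 at -0.80. The 9 endothelial markers had medians of 3.78 and 4.42 and a median difference of 0.17 (percentile 73.6; 0.04 with equal array medians and 0.73 without genes of identical value), with TIE1 at 1.36, VWF at 0.81, CLDN5 at 0.78 and EMCN at -1.37. Of the lists without a percentile, antigen presentation had 4 measured genes, with ERAP2 at 1.61, B2M at -0.39, ERAP1 at -0.34 and TAPBP at 0.00. The drug efflux list had 1, MVP, which read 5.58 on both arrays, and no replication-dependent histone gene was named in the annotation table.

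Over the 28 lists with a percentile, 10 stood apart as lower and 1 as higher at equal mean level, where 1.4 would fall outside the central range by chance. At equal parental level 3 stood apart, all lower: homologous recombination, end joining with damage signalling, and G2 and mitosis. Neighbouring genes and genes of 1 pathway vary together, so these percentiles describe the 2 arrays only.

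Genes that were bright in parental cells read lower in radioresistant cells, ribosomal and housekeeping genes included. With the genes ranked by parental signal into 10 groups of equal size, the median of the brightest group was 6.83 in parental and 4.88 in radioresistant cells, a median difference of -2.06, and 80.4% were at least 2-fold lower. That ranking uses a term of the difference itself: ranked by the mean of both arrays, the median difference was -0.87 in the brightest group, -0.32 in the next and 0.00 in the one after. By parental signal, in the dimmest group the medians were 1.74 and 1.83. Ranked by the radioresistant signal, the medians of its brightest group were 5.70 in parental and 5.85 in radioresistant cells, a median difference of 0.09. Within the brightest parental group, the signals of the 1482 genes on the 2 arrays had a Spearman rho of 0.0976 across genes. In the sixth to the ninth group rho was 0.0885, 0.120, 0.0339 and -0.0229, in the third 0.297 and in the dimmest 0.826. These values cannot show whether a low rho was particular to the brightest group. The sixth to the ninth group had parental medians from 4.49 to 5.84, and the narrow range of parental signal within a group lowers rho. Setting the array medians equal shifted the median gene by -0.13 and loess shifted it by -0.21, so list medians closer to 0 than that have no firm direction. Of the 2185 lower genes 1950 were also among the 2071 lower genes after loess, and of the 529 higher genes 383 were among the 534 higher after it.

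**Figure D3:**
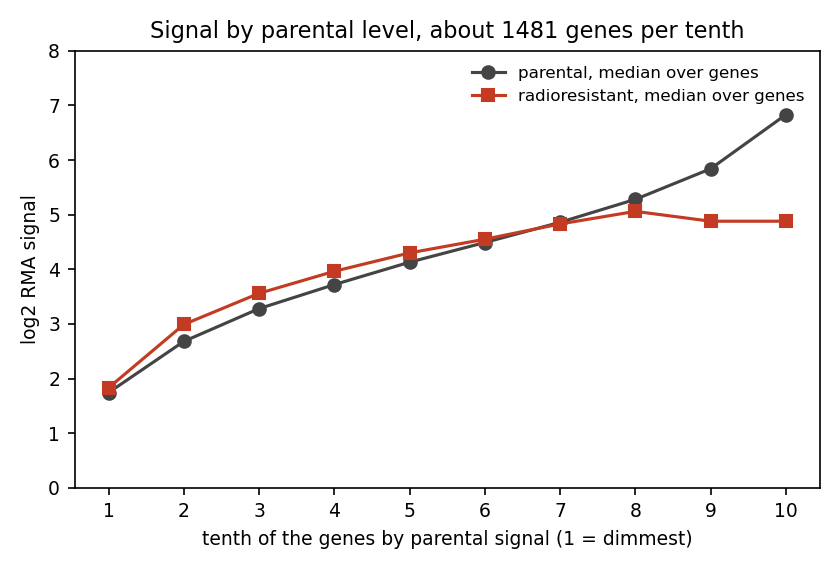
Median log2 RMA signal (y axis) on the parental array (circles) and the radioresistant array (squares), n = 1 array each, of genes in 10 groups of equal size ranked by parental signal (x axis, 1 the dimmest). The radioresistant median is slightly higher in the dimmer groups (4.13 and 4.30 in the fifth) and lower in the ninth (5.84 and 4.88) and the tenth (6.83 and 4.88).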

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

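Of the tests below, all but quantile normalisation and loess were chosen after the result was seen, and so was the bound their values are set against.

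Probe sets without a gene symbol entered the comparisons over all probe sets but no gene value, gene count or list. They showed differences between the arrays too. Of the 7624 at or above the genes' median level, 1123 (14.7%) were at least 2-fold higher and 1610 (21.1%) at least 2-fold lower in radioresistant cells, against 7.14% and 29.5% of genes.

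Bright genes, TFF1, GREB1, KRT19 and EPCAM among them, were lower on the radioresistant array. A narrower signal range that keeps the order of genes is argued against for estrogen receptor genes, whose median after quantile normalisation was -1.27 (percentile 0.00) and after loess -1.46 (0.01), while luminal genes, at -0.68 (2.25) and -0.30 (33.5), do not decide it. Loss of bright signals whatever the gene, from RNA quality or labelling, is consistent with both lists, since among genes of equal parental level they stood at percentiles 27.32 and 86.69. Base composition of regions stays open. For the genes brightest by mean level, the median difference was -0.77 (bootstrap interval -0.96 to -0.64) on chromosomes known for GC-rich genes. It was -1.41 (-1.74 to -0.91) on those known for AT-rich genes. A radioresistant sample of cells other than MCF-7 stays open as well. Genes of 2 neighbourhoods commonly amplified in MCF-7 were chosen after low values were seen there. At equal parental level they stood at percentile 3.74 on chromosome 17, 67.09 on chromosome 20 and 0.75 together. Without BRIP1 and PARD6B they stood at 7.84 together, which decides nothing. Loss of the luminal programme during selection stays open too, as 1 array per group cannot separate it from these. At equal parental level no fall particular to luminal markers was seen. Their median was -1.05, against -1.52 in random lists, and against their neighbours they stood high, at percentile 98.17. After quantile normalisation they stood low, at 2.25 among random lists of equal mean level.

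Homologous recombination, end joining and mitosis genes were lower than equally bright genes. A narrower signal range with the order of genes kept is argued against, since after quantile normalisation 3 of the 3 lists stood under 0.0893 (percentile 2.5 divided by the 28 lists they were singled out of), with medians of -1.88, -1.52 and -1.67. Homologous recombination stood at percentile 0.00 at equal parental level and at 0.01 against its neighbours, both under the same bound. That bound replaced one of 2.5 that took no account of this choice. The list thus fell further than equally bright genes and than its neighbours on these arrays. However, the first percentile is the value that singled the list out, and random lists take no account of genes that vary together. These percentiles therefore do not decide on loss of bright signals whatever the gene, or on base composition of regions. For end joining and mitosis both stay open as well, at 1.78 and 0.70 and at 0.17 and 1.19. Fewer dividing cells stay open as an explanation for all 3 lists, homologous recombination included. G1/S genes, at percentile 30.06 at equal parental level, do not decide it. Base composition or length of the transcripts themselves and radioresistance itself stay open, untested.

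Many probe sets, 12074 or 27.1%, had the same value on both arrays to 2 decimals, 126.3 times the mean of 95.6 in the neighbouring steps of 0.01. These values should therefore not be read as measured equality of the genes. Whether a step of the authors' summary that sets both arrays to one value produced them stays open. The partner probe sets below cannot decide it, since such a step could also act mainly on probe sets that differ little. In genes with a pair of probe sets, partners of a probe set with identical values had a median absolute difference of 0.19, against 0.41 for the other partners (bootstrap interval of the gap -0.30 to -0.07). They had identical values themselves in 33.6% of cases against 23.2%, and were at least 2-fold apart in 15.7% against 25.8%. Identical values thus went with smaller differences of the same gene without excluding large ones, and no biological explanation was tested.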

How the results depend on the processing

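Of the alternatives below, matching on the parental level, leaving out genes with identical values and protein-coding genes only were chosen after the result was seen.

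Medians that changed sign were those of mesenchymal genes (-0.02 with equal array medians, -0.01 after loess), basal markers (-0.0869 after loess) and fibroblast markers (-0.105 after quantile normalisation, -0.09 with equal medians, -0.239 after loess), none of which stood apart. Higher genes numbered 937 after quantile normalisation, 952 without a filter on level, 239 above the 75th percentile, 1206 at 1.5-fold, 93 at 3-fold and 299 among protein-coding genes, and lower genes 1416 above the 75th percentile and 1423 at 3-fold. Filters and thresholds change the number of genes counted. Among protein-coding genes the balance of directions changed too: 13.2% of the genes past 2-fold were higher, against 19.5% in the main count. For this and for quantile normalisation the cause was not tested. The other 16 counts stayed within 1.5 times. No list changed its call with equal array medians, loess or the brightest probe set. Matched on the parental level, lists no longer apart were estrogen receptor response (-1.30), p53 (-0.785), excision and mismatch repair (-1.175), G1/S (-1.565), NF-kB (0.34), cholesterol (-1.12), ribosomal proteins (-1.3825) and housekeeping (-1.185), where the median of the random lists was lower than at equal mean level, except for NF-kB. With only genes above the median level, estrogen receptor response (-1.145), p53 (-0.785) and housekeeping (-1.51) were no longer apart, with fewer genes tested. By the mean of members, p53 (-0.8942) and excision and mismatch repair (-1.0661) were no longer apart, and NRF2 (-1.1621) and oxidative phosphorylation (-1.7036) were. Without identical values, p53 (-0.935) and excision and mismatch repair (-1.195) were no longer apart, and BCL2 (-0.885) and endothelial markers (0.73) were. Random lists without matching set apart luminal (-1.05), NRF2 (-0.815), fatty acid (-0.295), unfolded protein (-0.44) and oxidative phosphorylation (-1.24) genes, and quantile normalisation luminal genes (-0.68). Where none is given, the cause was not tested. Over lists and alternatives, 217 values kept the call without a reversed sign, 6 changed sign, 15 lost the call and 10 gained it. The 217 include lists whose main median was neither positive nor negative, so these had no direction to keep. Stemness genes, among them, had a median of 0.275 after quantile normalisation and -0.13 with equal array medians. Of 149 named genes, loess moved 31, quantile normalisation 17 and the brightest probe set 4 by more than 1.5-fold. Lists with fewer than 5 genes above the median level gave no value there. Leaving out a replicate was not possible with 1 array per group, and signal over background was not analysed.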

Other observations

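The gene families, chromosome sets and neighbourhoods here, and all tests on them, were chosen after the data were seen.

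Of families outside the fixed lists, microRNA precursors, keratin-associated proteins and long intergenic non-coding RNAs stood above random lists of equal mean and of equal parental level, at percentiles of at least 99.98. Their median signals were low, at 2.75, 2.94 and 3.05 in parental and 3.15, 3.40 and 3.40 in radioresistant cells. These lay under the array medians of 3.58 and 3.71, and signal over background was not analysed. Of 1037 microRNA precursor genes, 181 were at least 2-fold higher and 35 at least 2-fold lower in radioresistant cells, with a median of 0.20 (0.06 after loess, 0.06 in random lists of equal parental level). MIR31 read 3.35 and 7.45, a difference of 4.10. Keratin-associated protein genes, which are not known to be expressed in breast cells, had 18 of 85 at least 2-fold higher and none at least 2-fold lower. Their median was 0.52 (0.29 after loess, 0.08 in random lists of equal parental level). Long intergenic non-coding RNAs had a median of 0.23 over 457 genes, which was 0.02 after loess, against 0.14 in random lists of equal parental level. Small nucleolar and Cajal body RNAs had 11 of 21 at least 2-fold lower and a median of -1.02. They stood apart as lower at equal mean level (percentile 0.82) and did not stand apart at equal parental level (percentile 8.37). The 491 ZNF genes had 90 at least 2-fold lower, 8 at least 2-fold higher and a median of 0.00 (percentile 48.7), inside the range of other genes of their level. Only 1 olfactory receptor gene was measured.

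Genes near BCAS3 and BRIP1 on chromosome 17, a region commonly amplified in MCF-7, had a parental median of 7.38 and a radioresistant median of 4.59 over 20 genes, of which 13 were at least 2-fold lower. Their median difference was -2.345, against -1.625 in random lists of equal parental level. This put them at percentile 3.74, so they did not stand apart. APPBP2 read 10.87 and 5.74, TRIM37 9.99 and 5.15, and MED13 9.10 and 5.65, while TBX4 differed by 1.07 and CA4, EFCAB3 and GDPD1 had identical values. Near ZNF217 and BCAS1 on chromosome 20, 4 of 9 genes were at least 2-fold lower and the median was -0.67, against -0.94 in random lists of equal parental level. There PARD6B read 9.11 and 2.76 and ZNF217 8.57 and 3.71, while BCAS1 read 5.05 and 4.75. The end genes of both neighbourhoods were chosen after lower values had been seen there.

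Differences were also arranged along the genome. After the trend on parental level was taken out, adjacent coding genes had residuals that correlated with a Spearman rho of 0.170 over 11882 pairs, against a highest value of 0.0653 in 1000 shuffles within chromosomes. The mean of chromosome medians was 0.157 for 5 chromosomes known for GC-rich genes (16, 17, 19, 20 and 22) and -0.098 for 5 known for AT-rich genes (4, 5, 13, 18 and X), with an exact two-sided permutation p of 0.0079, the smallest that 252 arrangements can give. That p compares only these sets, chosen after the data were seen, and leaves out all other chromosomes. The lowest median of the GC-rich set, 0.1175 on chromosome 16, lay above every chromosome outside it. Low medians were not particular to the AT-rich set: chromosomes 15 and 14, in neither set, had -0.16 and -0.12, and X had 0.00. Set against their neighbours, ribosomal protein genes stood at percentile 0.00 and cholesterol genes at 2.40, beside homologous recombination, end joining and mitosis genes, while excision and mismatch repair genes stood at 22.5. Luminal markers stood high, at 98.17, with a median of 0.42 over their neighbours, as did mesenchymal (99.29), stemness (97.84), leukocyte (98.05) and hypoxia and glycolysis genes (99.73).

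Probe sets of the same gene gave partly different answers. In 529 genes with exactly 2 probe sets, the differences correlated across genes with a Pearson r of 0.469 and a Spearman rho of 0.448, and the median gap between them was 0.48.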
